A study of Mus musculus with 16 samples.

How the data were processed

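Total RNA from mouse embryonic stem (ES) cells was profiled on 16 Affymetrix mouse expression arrays, 1 array per sample. The samples formed 6 groups by genotype (WT or KO, homozygous for an inactivated allele) and state (growing, 2 h or 24 h after gamma irradiation, IR). Each genotype had 3 arrays of growing cells, 3 at 2 h and 2 at 24 h. Per the labels, ES cells grew with LIF on mitomycin-treated mouse embryonic fibroblasts. Before lysis, trypsinised cells were left for 1 h on gelatin-coated dishes so that fibroblasts would be removed. RNA was extracted with Trizol, and 5 µg of each sample went through 1 round of amplification into biotin-labelled targets. The labels give a dose of 8 Gy for the 2 h samples, and the dose of the 24 h samples is not given in the sources used here.

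The values deposited by the authors are intensities, 1 per probe set and array, on a linear scale and above 0. On every array the mean intensity after trimming 2% of probe sets at each end was 100, so the arrays had been scaled to 1 constant. They had not been centred by gene. The software that summarised probes into probe sets, its version and the probe set definitions are not given in the sources used here, and that summary step stays unknown. Scale, centring and direction followed from the values. The other deposited files are the array instrument's settings, per the file headers, and hold no expression value. They served to sort arrays into 4 hybridisation runs on 2 days. Run 4, the only one on the second day, held the 4 arrays numbered replicate 3.

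Array medians of the intensity were 30.8, 29.0 and 34.9 for WT growing replicates 1, 2 and 3, and 29.6, 28.0 and 28.6 for WT at 2 h. They were 34.7 and 34.2 for WT at 24 h. In KO they were 26.7, 30.4 and 28.7 for growing cells, 35.0, 31.9 and 29.5 at 2 h, and 37.4 and 33.7 at 24 h. The ratio of 3' to 5' signal ranged from 1.02 to 1.28 for actin and from 0.743 to 0.883 for Gapdh. The 18S rRNA control signal ranged from 41.3 to 2942 and exceeded 300 on 2 arrays, WT growing replicate 1 (976) and KO 2 h replicate 2 (2942). Pearson correlations between arrays over the probe sets lay between 0.939 and 0.985. No pair of arrays held identical values. Precision is limited by the number of arrays, 2 or 3 per group.

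Of 22690 probe sets, 64 controls were left out. The platform annotation gave 1 gene symbol for 20393 probe sets, several for 691 and none for 1606. Only probe sets with 1 symbol were named. No symbol changed when looked up by Entrez identifier (0 updates). A gene table of assembly GRCm38.p6 served only for gene names, chromosome membership and the order of genes. The measurement of the inactivated gene is not reported here, and the genotype labels were taken as given. Bax had no tested probe set.

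Values were analysed as log2(intensity + 16) in R 4.3.3 with limma 3.58.1. A probe set was tested where the mean of at least 1 group exceeded the 30th percentile of all values, which was 4.80 on the log2 scale and corresponds to an intensity of 11.9. This left 17736 probe sets and 10252 genes, 2457 of the probe sets having an identifier that marks possible cross-hybridisation. Because of the added 16, a log2 change understates the change of dim genes. One model with 6 group means was fitted (lmFit, then eBayes with an intensity trend), with 10 residual and 8.55 prior degrees of freedom. Two-sided p-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. The 9 comparisons were KO against WT in each state, each irradiated group against growing cells of its genotype, and the genotype-by-irradiation interaction at 2 h and at 24 h.

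For gene-level statements the tested probe set with the highest mean over the 16 arrays stood for its gene. The 26 gene lists were primitive endoderm, visceral endoderm, parietal endoderm, pluripotency, epiblast and priming, mesoderm and primitive streak, neuroectoderm, trophectoderm, 2-cell-like, germline and methylation-sensitive, imprinted, feeder fibroblast, p53 targets, apoptosis regulators, DNA repair, G1/S and DNA replication, G2/M and mitosis, integrated stress response, immediate-early and dissociation, hypoxia and glycolysis, interferon response, sterol synthesis, FGF and ERK signalling, and X and Y linked sex markers, with 2 more that are not described here. Each list was tested against all other genes with limma's camera (preset inter-gene correlation 0.01), with adjustment over the 26 lists of a comparison. An estimated correlation was an alternative, as was fry, which tests a list for a shift up or down by itself and not against other genes. Genes were counted after adjustment over all probe sets and also adjusted over the list alone.

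Genes were named by rule. For KO against WT in growing cells these were the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05 whose groups did not overlap, and elsewhere 5 and 5. Nras was always named, as were Gata6, Gata4, Sox17, Sox7, Pdgfra, Dab2, Pou5f1, Nanog, Sox2, Klf4, Zfp42, Cdkn1a, Mdm2, Ccng1 and Bax. Each described list added up to 4 members that passed and up to 2 bright members that did not. The lists, comparisons, tests, naming rule and most alternative settings were fixed before the data were examined. These settings were quantile normalization, no filter or the 50th percentile, an added 1 or 64, only the groups compared, the replicate number as a fixed or random block, the run as a block, no trend, array weights, a 2-fold minimum, leaving out cross-hybridising probe sets, the mean over a gene's probe sets, and leaving out each array. The hybridisation day as a block, leaving out the second day, leaving out the 2 arrays with high 18S signal, and a genotype comparison pooled over all states were chosen after seeing the data.

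Replicate numbers were checked by correlating the deviations of same-numbered arrays from their group means. For WT at 2 h against growing cells all 3 pairs correlated (r from 0.198 to 0.292), each pair sharing its hybridisation run, and the numbers were taken to pair these arrays. The model fixed beforehand has no pairing, which entered as an alternative. The code was tested on simulated data drawn for the 17736 probe sets with known changes. Of probe sets changed by 1 log2 unit it recovered 86.6% for KO against WT in growing cells, 77.6% at 2 h and 58.2% at 24 h. The shares were 86.6% for WT and 79.1% for KO at 2 h against growing, 80.6% for WT and 71.6% for KO at 24 h, and 25.4% and 32.8% for the interactions at 2 h and 24 h. Of changes of 0.5 log2 units it recovered 20.9% for KO against WT in growing cells and 4.48% and 0% for the interactions at 2 h and 24 h. Between 2 and 13 unchanged probe sets were called per comparison.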

Results

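Mouse embryonic stem (ES) cells of 2 genotypes, WT and KO, were compared. The cell lines had been made from single blastocysts of an intercross of heterozygous mice. RNA was measured in growing cells and at 2 h and 24 h after gamma irradiation, which breaks DNA. The labels number the samples of a group as experiments and do not say that they came from separate cultures or lines, so p-values measure only the spread between these samples, which may be technical. Values are given as mean intensity ± SD in scaled units (n = 3 for growing and 2 h groups, n = 2 for 24 h groups), and changes as log2(intensity + 16) ± SE. Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

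The first comparison asked which transcripts differed between KO and WT ES cells under growth conditions, and whether genes of the primitive endoderm were among them. Ccnb1ip1, a ubiquitin ligase known from meiotic recombination, was higher in KO, at 93.7 ± 5.96 against 9.77 ± 4.23 (2.10 ± 0.18, adjusted p = 1.74e-06). Cubn, the endocytic receptor cubilin of the visceral endoderm, stood at 42.0 ± 13.6 against 1.94 ± 0.36 (1.67 ± 0.20, adjusted p = 0.000313). This probe set of Cubn has an identifier that marks possible cross-hybridisation. Another had 0.93 in growing cells, 0.91 at 2 h and 1.46 at 24 h, and did not pass in any state. Srgn, which encodes the proteoglycan serglycin, was higher as well, at 49.9 ± 13.4 against 7.54 ± 6.30 (1.50 ± 0.29, adjusted p = 0.0328). WT levels of these 3 genes lie below the filter, so the sizes follow the added 16. With an added 64 or 1 they were 1.10 or 3.20 for Ccnb1ip1, 0.68 or 3.83 for Cubn and 0.67 or 2.79 for Srgn, which did not pass with 64 (adjusted p = 0.114). Klhl13, an adaptor of a cullin ubiquitin ligase, was lower at 453 ± 91.9 against 928 ± 90.7 (-1.02 ± 0.16, adjusted p = 0.00577).

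Further genes higher in growing KO cells were Inhbb, an activin subunit (1.51), Etv4, an ETS factor induced by FGF signalling (1.13), D1Pas1, an RNA helicase (1.08), Fxr2, an RNA-binding protein of the FMRP family (1.02), Parp12 (0.93), the histone demethylase Kdm2b (0.83) and Zbtb44 (0.68). Their adjusted p-values ran from 0.0114 for Fxr2 to 0.0374 for Parp12 and Kdm2b. Lower in KO were Arhgap6 (-1.39), Fxyd6, a regulator of the sodium pump (-1.23), the repressor Zbtb16 (-1.12), Plac8 (-1.08), Pttg1, which encodes securin (-1.06), the Hedgehog receptor Ptch1 (-0.98), Tcl1, a cofactor of Akt (-0.97), the hormone precursor gene Trh (-0.95) and the ubiquitin ligase gene Trim13 (-0.94). Their adjusted p-values ran from 0.00577 for Trim13 to 0.0493 for Plac8. Over 30 or 31 other fits these calls were lost in 3 (Trh and Trim13) to 19 (Zbtb16), Etv4, Fxyd6 and Zbtb44 in 12 and Kdm2b in 13, and Arhgap6 ranged from -2.58 to -0.61. Another probe set of Inhbb had 0.59 and did not pass. Of 3 probe sets of Arhgap6, from -1.39 to -0.45, only 1 passed, and of 3 of Pttg1 2 passed. D1Pas1 (0.63) and Ptch1 (-0.85) each had another probe set that did not pass.

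Nras, which encodes a small GTPase of the RAS family, had 3 probe sets that differed in strength. All 3 had higher means in KO in every state, but only 1 of them passed. It was higher by 0.78 ± 0.12 in growing cells (233 ± 10.5 against 130 ± 14.8, adjusted p = 0.00565). Its difference was 0.85 ± 0.12 at 2 h (adjusted p = 0.00240) and 0.81 ± 0.14 at 24 h (adjusted p = 0.0426). The probe set that stood for Nras by rule had 0.69 ± 0.17 in growing cells (adjusted p = 0.102), 0.57 at 2 h and 0.35 at 24 h, and the remaining one 0.61 in growing cells (adjusted p = 0.241). Neither passed in any state.

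Genes of the primitive endoderm, the extraembryonic lineage that lines the blastocyst cavity, lay above the other genes in growing KO cells. Of 23 measured members, 2 were higher (Cubn and Srgn), 0 were lower and the rest did not pass, and 4 were higher when adjusted over the list alone. The median was 0.31 (camera adjusted p = 0.00122), with adjusted p = 0.467 with an estimated correlation. The bright members Sparc (0.31) and Lamc1 (0.63) did not pass. Nor did the lineage regulators and markers Gata6 (0.36), Gata4 (0.31), Sox7 (0.32), Sox17 (-0.02), Pdgfra (0.31) and Dab2 (0.71, adjusted p = 0.262). Other probe sets of Dab2 and Gata4 gave values of opposite sign, down to -0.10 and -0.05. Runs 1 and 4 held both genotypes, and within them the list's median was 0.28 and 0.21. It was 0.34 with the run as a block (adjusted p = 1.10e-05).

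The FGF and ERK signalling list had a median of 0.21 (adjusted p = 0.0333; adjusted p = 0.425 with an estimated correlation). Of its 19 genes, only Etv4 passed, with 2 higher and 1 lower when adjusted over the list alone, while Fgf4 (0.49) and Etv5 (0.24) did not pass. This list was no longer called after quantile normalization (adjusted p = 0.0515). The epiblast and priming list had a median of 0.23 over 13 genes (adjusted p = 0.0491; adjusted p = 0.442 with an estimated correlation). None of its members passed over all probe sets, 2 were higher when adjusted over the list alone, and the methyltransferase gene Dnmt3b (0.10) and Nodal (-0.25) did not pass. Its adjusted p was 0.0706 with the run as a block. Of 27 measured pluripotency genes, 1 was lower (Tcl1), 0 were higher and 2 were lower when adjusted over the list alone, with a median of 0.04 (adjusted p = 0.459). The core factors Pou5f1 (0.04), Sox2 (-0.02), Nanog (-0.42), Klf4 (0.33) and Zfp42 (0.03) did not pass.

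The other lists gave no call in growing cells. The visceral endoderm list (14 genes, Cubn higher, 2 adjusted over the list alone) had a median of 0.07 (adjusted p = 0.140). Medians were -0.23 for 13 neuroectoderm genes and -0.17 for 23 imprinted genes (adjusted p = 0.140 each), 0.08 for 15 germline and methylation-sensitive genes, -0.17 for 13 parietal endoderm genes, -0.01 for 25 apoptosis regulators and -0.08 for 37 p53 targets (adjusted p = 0.819 each). For the germline list the mean was -0.03, opposite to its median and test, and for the parietal endoderm and apoptosis lists the test pointed up while median and mean were below 0. The 6 sex markers had a median of 0.04 (adjusted p = 0.459). Feeder fibroblast genes (22 measured) had a median of -0.09 (adjusted p = 0.819), 0.14 within run 1 and -0.39 within run 4, and without WT growing replicate 3 it was 0.29 (adjusted p = 0.0310). On the second hybridisation day the mean of this list was higher, at 6.50 ± 0.29 (SD, 4 arrays) against 5.95 ± 0.29 (12 arrays) on the log2 scale.

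In total 44 probe sets differed between KO and WT growing cells, 22 higher and 22 lower (20 and 18 named genes), 9 and 10 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1878, where 887 would be expected by chance. With the hybridisation run as a block 144 passed, without the second hybridisation day 6, and without the 2 arrays of high 18S signal 23. Leaving out 1 array gave 6 without KO growing replicate 1, 9 without KO growing replicate 3, and 27 without WT growing replicate 1 or KO 2 h replicate 1.

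**Figure D1:**
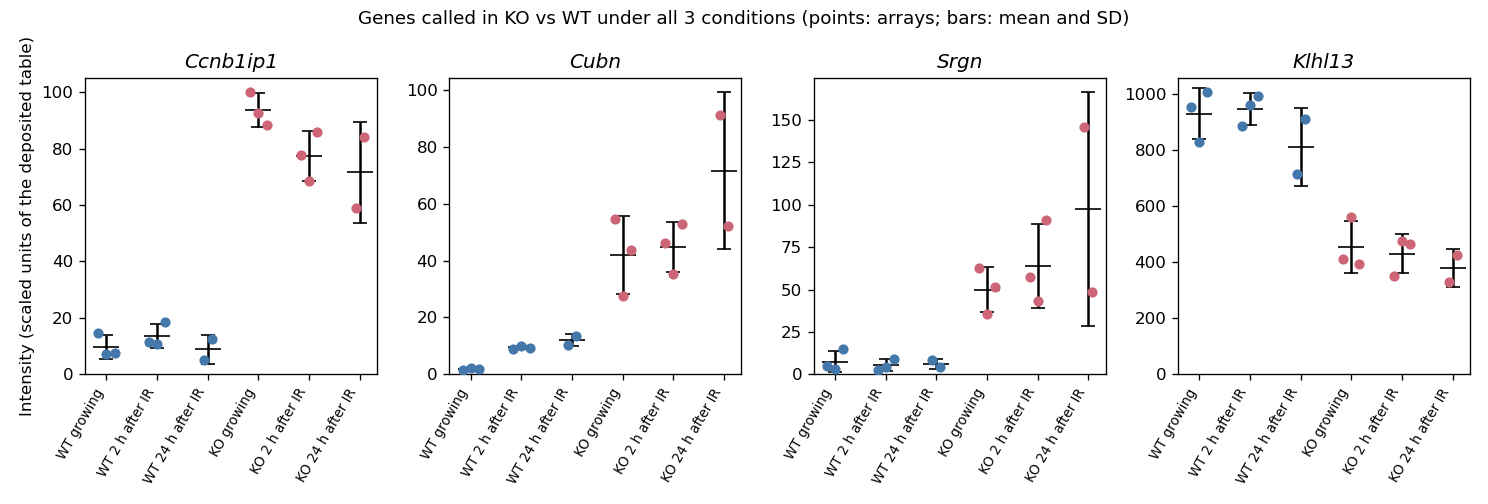
Intensity in scaled units of Ccnb1ip1, Cubn, Srgn and Klhl13 in the 6 groups; points are arrays and bars the mean with SD. In each state the KO arrays of the first 3 genes lie above the WT arrays, and those of Klhl13 lie below.

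**Figure D2:**
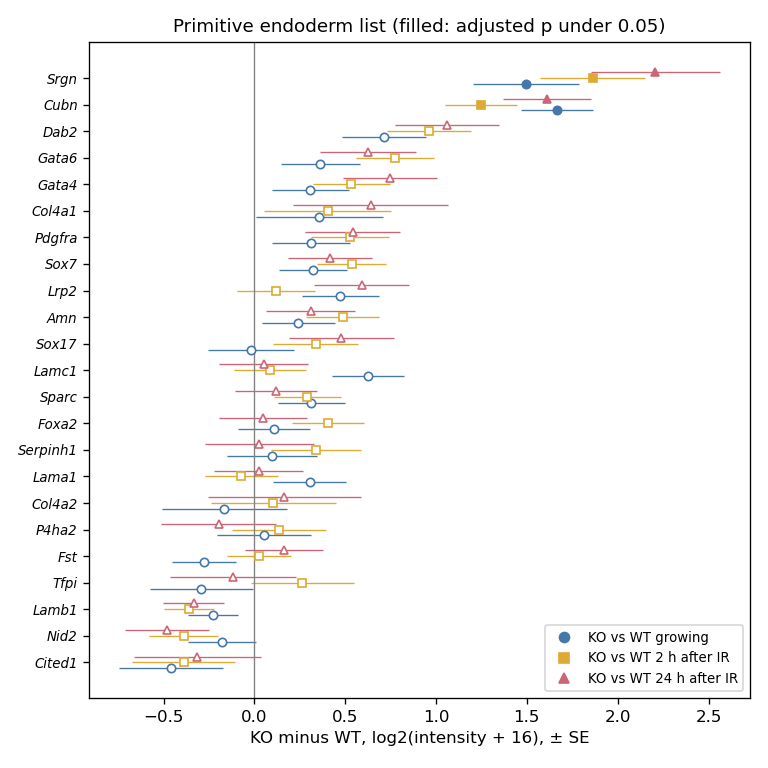
KO minus WT difference of the 23 measured primitive endoderm genes in log2(intensity + 16), with SE, for growing cells and 2 h and 24 h after irradiation; filled points have an adjusted p under 0.05. Cubn and Srgn are the filled genes in each of the 3 states.

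Irradiated KO and WT cells were compared next, to ask how the genotypes differ after DNA damage. At 2 h genes again higher in KO were Srgn (1.86 ± 0.29, adjusted p = 0.00482), Inhbb (1.76 ± 0.26), Ccnb1ip1 (1.66 ± 0.18) and Cubn (1.25 ± 0.20), joined by Myo7a, an unconventional myosin (1.31 ± 0.20, 34.9 ± 3.39 against 4.81 ± 4.99). Where WT levels are that low, size and order follow the added constant, as for Srgn (0.86 with an added 64 and 3.39 with 1). Lower in KO were Arhgap6 (-1.44), Ptch1 (-1.19), Utrn, which encodes utrophin (-1.13), the cell-surface proteoglycan Gpc3 (-1.12) and Klhl13 (-1.12). Further probe sets of Arhgap6 (up to -0.77), Ptch1 (-0.98) and Utrn (-0.67) did not pass. Mki67, a marker of cycling cells, was lower at 223 ± 17.5 against 344 ± 17.6 (-0.59 ± 0.11, adjusted p = 0.0238).

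Genes of sterol synthesis lay lower in KO at 2 h, with a median of -0.30 over 14 genes (camera adjusted p = 0.000513; adjusted p = 0.306 with an estimated correlation). None of them passed singly, and Hmgcs1 (-0.37) and Fdps (-0.20) were the brightest. The primitive endoderm list had a median of 0.34 (adjusted p = 0.0127; adjusted p = 0.471 with an estimated correlation). In it Srgn and Cubn were higher, 0 genes were lower and 5 were higher when adjusted over the list alone, while Gata6 (0.77), Gata4 (0.53), Sox7 (0.54), Pdgfra (0.53) and Dab2 (0.96, adjusted p = 0.0709) did not pass. Its median was 0.09 within run 2, where the other genes had 0.10, and 0.24 within run 4, while the feeder fibroblast list had 0.41 and -0.52 there (-0.06 over all arrays compared). A model with the run as a block gave 0.23 (adjusted p = 0.0191). The list was not called without WT 2 h replicate 1 (0.06, adjusted p = 0.182) or without KO 2 h replicate 3 (0.30, adjusted p = 0.0919).

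Mesoderm and primitive streak genes had a median of 0.35 at 2 h (14 genes, adjusted p = 0.0127; adjusted p = 0.306 with an estimated correlation). None passed, and the brightest were Bmp4 (0.56) and Eomes (0.28). Visceral endoderm genes had 0.27 (14 genes, adjusted p = 0.0253; adjusted p = 0.306 with an estimated correlation), with Cubn higher, as in the primitive endoderm list that shares it, while Apoe (-0.11) and Apoa2 (0.26) did not pass. The G2/M and mitosis list had a median of -0.09 (31 genes, adjusted p = 0.0253; adjusted p = 0.493 with an estimated correlation), with Mki67 lower and 2 lower when adjusted over the list alone. Cdc20 (-0.14) and Ube2c (-0.29) did not pass. DNA repair genes had -0.07 (30 genes, adjusted p = 0.0430; adjusted p = 0.453 with an estimated correlation), with 1 lower when adjusted over the list alone, while H2ax (-0.26) and Msh6 (-0.22) did not pass. The G2/M list (adjusted p = 0.203), the DNA repair list (0.0771) and the visceral endoderm list (0.0605) were not called with the run as a block.

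At 2 h, 70 probe sets differed, 35 higher and 35 lower (31 and 29 named genes), 16 and 14 of them by at least 2-fold, against 2636 at an unadjusted p under 0.05. The count was 187 with the run as a block, without the second day 4, and without the 2 arrays of high 18S signal 41. It was 25, 28, 29 and 32 without WT 2 h replicate 3, WT 2 h replicate 2, KO 2 h replicate 3 and WT 2 h replicate 1, and 28 and 43 without KO 2 h replicates 1 and 2.

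At 24 h after irradiation the same direction held for Srgn (2.21 ± 0.36, adjusted p = 0.0152), Ccnb1ip1 (1.82 ± 0.22) and Cubn (1.61 ± 0.24), which were higher in KO. Trh (-1.22 ± 0.19, adjusted p = 0.0122), Klhl13 (-1.07 ± 0.19) and Rpgrip1, which encodes a protein of the photoreceptor cilium (-0.89 ± 0.16, adjusted p = 0.0435), were lower. A dimmer probe set of Rpgrip1 gave -0.25 and did not pass. The lineage regulators Gata6 (0.63), Gata4 (0.75), Sox17 (0.48) and Dab2 (1.06, adjusted p = 0.246) and the core factors Pou5f1 (0.19), Nanog (-0.52), Sox2 (-0.15), Klf4 (0.31) and Zfp42 (-0.32) did not pass.

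The primitive endoderm list had a median of 0.16 and a mean of 0.36 at 24 h (adjusted p = 0.00478; adjusted p = 0.388 with an estimated correlation), with Srgn and Cubn higher, 3 when adjusted over the list alone and 0 lower. With the run as a block it was not called (0.10, adjusted p = 0.109), and in run 3, the only one with both genotypes at 24 h, its median was 0.01 and that of the feeder fibroblast list 0.25 (0.14 over all arrays compared). It was also not called without KO 24 h replicate 1 (0.12, adjusted p = 0.334) or WT 24 h replicate 1 (0.01, adjusted p = 0.117). FGF and ERK signalling genes had a median of 0.27 (adjusted p = 0.0300; adjusted p = 0.202 with an estimated correlation), with 1 higher when adjusted over the list alone, and Fgf4 (0.32) and Etv5 (0.07) did not pass. Medians were 0.19 for epiblast and priming genes (2 higher adjusted over the list alone), 0.28 for the 6 2-cell-like genes, 0.31 for mesoderm and primitive streak genes (1 higher adjusted over the list alone) and -0.22 for 17 interferon response genes (2 lower adjusted over the list alone). Each had an adjusted p of 0.0333, and adjusted p = 0.286 with an estimated correlation. The visceral endoderm list had 0.19 (2 higher adjusted over the list alone, adjusted p = 0.0333; adjusted p = 0.202 with an estimated correlation). Outside the primitive and visceral endoderm lists no member of these lists passed over all probe sets. Bright members that did not pass were the interferon-induced membrane protein gene Ifitm1 (-1.04), Eif1a (0.29), Dnmt3b (-0.02) and Bmp4 (0.46). After quantile normalization the epiblast, 2-cell-like, visceral endoderm and interferon lists (adjusted p = 0.0522 each) and the mesoderm list (0.0762) were not called. With the run as a block 2 of the 7 lists called at 24 h were lost, the primitive endoderm list among them.

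At 24 h 11 probe sets differed, 5 higher and 6 lower, against 1701 at an unadjusted p under 0.05. The count was 23 with the run as a block, 25 after quantile normalization, 5 without the second day and 22 without WT 24 h replicate 2. The 3 comparisons used different arrays, and their calls overlapped. Growing and 2 h cells shared 10 higher and 14 lower probe sets, where 0.0434 each would be expected for independent lists. The 3 comparisons used the same estimate of the spread, so their lists were not independent. All 11 probe sets called at 24 h were called in the same direction in both other states. Among them were those of Ccnb1ip1, Cubn, Srgn, Supt16 (a histone chaperone subunit) and Nras, which were higher in KO, and those of Klhl13, Trh and Rpgrip1, which were lower.

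The response to irradiation was measured against growing cells of the same genotype. The labels name no unirradiated cells kept for the same 2 h or 24 h. Effects of irradiation therefore cannot be told apart from those of time in culture. At 2 h WT cells showed a short list of strongly induced genes, led by targets of p53, the transcription factor activated by DNA damage. Cdkn1a, the cell-cycle inhibitor p21, rose from 244 ± 103 to 784 ± 83.8 (1.69 ± 0.22, adjusted p = 0.000827). The kinase gene Plk2 rose from 185 ± 13.1 to 623 ± 112 (1.66 ± 0.15, adjusted p = 2.03e-05), and Mdm2, which encodes the ubiquitin ligase of p53, from 363 ± 67.3 to 1064 ± 219 (1.51 ± 0.17, adjusted p = 0.000195). The antiproliferative gene Btg2 (1.58 ± 0.17) and the phosphatidate phosphatase gene Lpin1 (1.61 ± 0.17) rose as well. The mitotic kinesin gene Kif18a was the only one to fall (-0.94 ± 0.19, adjusted p = 0.0490), a call lost in 22 of 31 other fits, with an adjusted p of up to 0.383.

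Of 37 measured p53 targets, 7 rose in WT at 2 h, 0 fell and the rest did not pass, and 12 rose when adjusted over the list alone. The median was 0.23 (camera adjusted p = 2.52e-16; adjusted p = 0.0227 with an estimated correlation). Ccng1 (0.57, adjusted p = 0.142) and Trp53inp1 (0.68) did not pass. Within runs 1, 2 and 4 the list's median was 0.24, 0.26 and 0.20, and with the run as a block its adjusted p was 1.18e-14. The integrated stress response list had 0.15 (20 genes, adjusted p = 0.0180; adjusted p = 0.853 with an estimated correlation), with Sesn2, itself a p53 target, raised by 0.78 ± 0.14. Hspa5 (0.21) and Asns (0.15) did not pass. G1/S and DNA replication genes had a median of 0.10 (29 genes, adjusted p = 0.0117; adjusted p = 0.853 with an estimated correlation), with no member passing, among them Pcna (0.12) and Mcm7 (0.16). Both lists were not called after quantile normalization (adjusted p = 0.131).

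In KO cells at 2 h the largest rises were in Btg2 (1.73 ± 0.17, adjusted p = 5.29e-05), Lpin1 (1.68 ± 0.17), Cdkn1a (1.64 ± 0.22, from 187 ± 14.4 to 623 ± 90.7), Plk2 (1.50 ± 0.15) and Ddit4, an inhibitor of mTOR signalling (1.45 ± 0.18). Mdm2 rose by 1.14 ± 0.17 (adjusted p = 0.00371), while Ccng1 (0.65, adjusted p = 0.0704) and Trp53inp1 (0.82) did not pass. Of the p53 targets 8 rose, 0 fell, and 14 rose when adjusted over the list alone, with a median of 0.35 (adjusted p = 4.29e-15; adjusted p = 0.0301 with an estimated correlation). The AP-1 gene Fosl1 was among them (1.15 ± 0.19, adjusted p = 0.0119). The list's median was 0.47 and 0.33 within the 2 runs that held both groups, and with the run as a block its adjusted p was 3.54e-12.

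Pluripotency genes had a median of -0.16 in KO cells at 2 h (27 genes, adjusted p = 0.000199; adjusted p = 0.143 with an estimated correlation), with no member passing, Sall4 at -0.35 and Dppa5a at 0.13. G2/M and mitosis genes had -0.10 (31 genes, adjusted p = 0.000172; adjusted p = 0.340 with an estimated correlation), with no member passing, Cdc20 at -0.04 and Ube2c at -0.05. FGF and ERK signalling genes had -0.14 (adjusted p = 0.0266; adjusted p = 0.202 with an estimated correlation), although Fosl1 rose, and 1 rose and 1 fell when adjusted over the list alone. Etv5 (-0.31) and Fgf4 (-0.14) did not pass. Mesoderm and primitive streak genes had 0.29 (adjusted p = 0.0262; adjusted p = 0.303 with an estimated correlation), with 2 raised when adjusted over the list alone, Eomes at 0.28 and Bmp4 at -0.30. These last 2 lists were not called after quantile normalization (adjusted p = 0.107 each), nor the mesoderm list with the run as a block (0.0589).

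At 2 h 26 probe sets changed in WT, 25 up and 1 down, and 19 in KO, all up, against 1436 and 1415 at an unadjusted p under 0.05. The 2 sets came from different arrays and shared 15 raised probe sets, where 0.0268 would be expected for independent lists. Both lists used the same estimate of the spread, so they were not independent. Over all probe sets the 2 responses had r = -0.096. The WT count was 17 without WT 2 h replicate 2 and 15 without the second day, and the KO count 11 without KO growing replicate 1 or without the second day. The difference between the genotypes in their 2 h response, tested as an interaction, gave 0 probe sets in limma, with a smallest adjusted p of 0.182 and 1763 at an unadjusted p under 0.05. Cdkn1a (-0.04 ± 0.31, adjusted p = 0.985), Mdm2 (-0.36 ± 0.24, adjusted p = 0.655) and Ccng1 (0.09 ± 0.19, adjusted p = 0.932) did not pass. Among the lists, G2/M and mitosis differed, with a median of -0.07 (mean -0.10, adjusted p = 0.0147; adjusted p = 0.750 with an estimated correlation), no member passing, and Cdc20 and Ube2c at -0.01 and -0.02. It was not called after quantile normalization (-0.03, adjusted p = 0.527) or without the second day (-0.12, adjusted p = 0.0809).

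**Figure D3:**
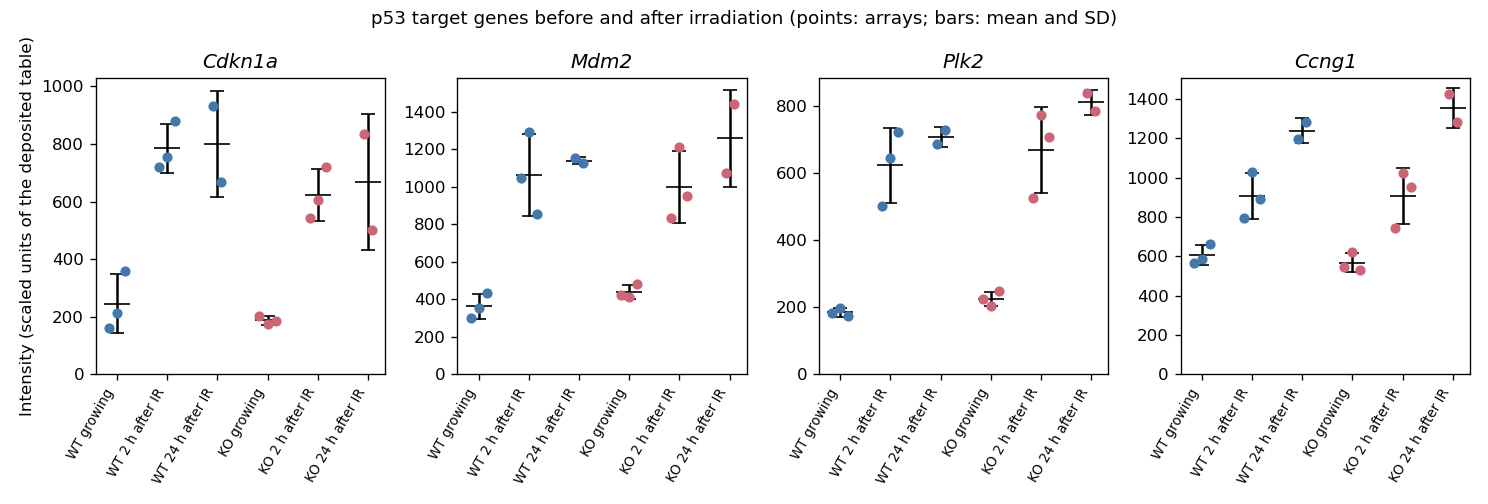
Intensity in scaled units of Cdkn1a, Mdm2, Plk2 and Ccng1 in the 6 groups; points are arrays and bars the mean with SD. All 4 genes are higher at 24 h than in growing cells of either genotype, Cdkn1a from 244 to 799.9 in WT and from 187 to 668 in KO.

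At 24 h the change was broad in both genotypes, with single p53 targets raised and single pluripotency genes lowered. In WT the largest rises were in Dcxr, a carbonyl reductase (59.9 ± 6.47 to 435 ± 174, 2.52 ± 0.24, adjusted p = 2.44e-05), Ddit4 (210 ± 26.7 to 898 ± 1.76, 2.02 ± 0.20), Cyba, a subunit of NADPH oxidase (2.02 ± 0.32), Rtkn (2.02 ± 0.26) and the tumour suppressor Rb1 (1.94 ± 0.25). The largest falls were in Msrb2, a methionine sulfoxide reductase (-1.68 ± 0.33), the kinase gene Pim2 (-1.66 ± 0.25), Slc27a2, a fatty acid transporter (-1.64 ± 0.30), Zfp428 (-1.54 ± 0.28) and Nacc1 (-1.52 ± 0.33). Cdkn1a (1.70), Mdm2 (1.62) and Ccng1 (1.02, adjusted p = 0.000432) were raised.

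Of the 37 p53 targets, 18 rose in WT at 24 h, 0 fell, and 19 rose when adjusted over the list alone, among them Plk2 (1.85), Btg2 (1.83) and Perp (1.74). The median was 0.53 (camera adjusted p = 1.03e-12; adjusted p = 0.0541 with an estimated correlation). Sesn2 (0.03) and Aen (0.02) did not pass. Of 27 pluripotency genes, 5 fell and 0 rose, 11 fell when adjusted over the list alone, and the median was -0.16 (adjusted p = 0.00113; adjusted p = 0.210 with an estimated correlation). Pou5f1, which encodes Oct4, fell from 1339 ± 76.2 to 904 ± 43.6 (-0.56 ± 0.14, adjusted p = 0.0167). Nr0b1 (-1.26), the RNA-binding Lin28a (-1.22), Gdf3 (-0.98) and Tcl1 (-0.64) fell, while Nanog (0.35), Sall4 (-0.47) and Dppa5a (0.21) did not pass. Within run 1 the medians were 0.94 for p53 targets and -0.46 for pluripotency genes, and with the run as a block the adjusted p-values were 4.59e-10 and 0.00122. The feeder fibroblast list had a median of 0.14 (adjusted p = 0.922) over all arrays compared and 0.86 within run 1.

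The integrated stress response list had a median of -0.19 in WT (adjusted p = 0.00363; adjusted p = 0.541 with an estimated correlation), with 1 gene raised and 6 lowered (2 and 7 adjusted over the list alone). The folate enzyme gene Mthfd2 (-1.37), the amino acid transporter Slc7a5 (-1.31) and the serine synthesis gene Psat1 (-1.13) fell, and Atf3 rose (1.24), a call lost in 14 of 31 other fits (adjusted p up to 0.325). Hspa5 (0.31) and Asns (-0.03) did not pass. Of 20 immediate-early and dissociation genes 4 rose (10 up and 1 down adjusted over the list alone), namely Btg2, Ccn1 (1.36), Atf3 and Jun (0.94), with a median of 0.39 (adjusted p = 0.00425; adjusted p = 0.529 with an estimated correlation). Ier2 (-0.50) and Jund (0.21) did not pass. Of 31 G2/M and mitosis genes 6 rose (11 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.00187; adjusted p = 0.529 with an estimated correlation), among them Hmmr (1.15), Anln (0.77), Bub1b (0.66) and Ccnb2 (0.57). Cdc20 (0.21) and Ube2c (0.12) did not pass.

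Further shifts in WT at 24 h concerned lineage and metabolic genes. Primitive endoderm genes had a median of 0.33 (adjusted p = 0.0410; adjusted p = 0.629 with an estimated correlation), with 4 raised (5 adjusted over the list alone), namely Cited1 (1.19), the collagen hydroxylase P4ha2 (1.18), the laminin gene Lamb1 (0.99) and Sparc (0.70), while Lamc1 (0.19) and Tfpi (0.45) did not pass. Without the 2 arrays of high 18S signal this list was not called (adjusted p = 0.168). Within run 1 its median was 0.23, while the feeder fibroblast list had 0.86 there. A contribution of fibroblasts was not tested here. Epiblast and priming genes had -0.30 (adjusted p = 0.0114; adjusted p = 0.283 with an estimated correlation), with the methyltransferase genes Dnmt3a (-1.34) and Dnmt3b (-0.99) lowered and Nodal (0.35) and Tead2 (-0.09) not passing. Hypoxia and glycolysis genes had 0.37 over 23 genes (adjusted p = 0.0286; adjusted p = 0.633 with an estimated correlation), with Ddit4 and the glucose transporter Slc2a1 (0.80) raised (3 adjusted over the list alone) and Ldha (0.01) and Aldoa (0.40) not passing. Sterol synthesis genes had -0.21 (adjusted p = 0.00973; adjusted p = 0.529 with an estimated correlation), with Fdps lowered (-0.42) and Hmgcs1 (0.20) and Fdft1 (-0.38) not passing.

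In KO cells at 24 h the median over all probe sets was 0.11 in the deposited scaling and -0.01 after quantile normalization. Changes in WT at 24 h, where that median was 0.03 in the deposited scaling, are given without subtraction. Those in KO at 24 h are given relative to 0.11, and the adjusted p-values test the change before this subtraction. The largest rises were in Ddit4 (1.96 ± 0.20, 184 ± 54.5 to 823 ± 256), Dcxr (1.81 ± 0.24), Tbc1d8 (1.75 ± 0.23), the matricellular gene Ccn1 (1.67 ± 0.26) and Plk2 (1.67 ± 0.17, adjusted p = 1.89e-05). The largest falls were in Mep1b, a subunit of the protease meprin (-1.91 ± 0.35, adjusted p = 0.00442), Pim2 (-1.82 ± 0.25), Slc27a2 (-1.62 ± 0.30), Zfp428 (-1.49 ± 0.28) and the adaptor gene Shf (-1.48 ± 0.21). Cdkn1a (1.60), Mdm2 (1.36) and Ccng1 (1.13, adjusted p = 0.000170) rose, and Pou5f1 (-0.52, adjusted p = 0.0735) did not pass.

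Of the p53 targets 22 rose in KO at 24 h and 0 fell (25 adjusted over the list alone, 20 after quantile normalization), among them Btg2 (1.67) and Perp (1.63), while Ei24 (0.10) and Sesn2 (-0.02) did not pass. The list's median was 0.66 above that of all probe sets (adjusted p = 1.60e-14; adjusted p = 0.0344 with an estimated correlation). Of the pluripotency genes 7 fell and 0 rose (8 adjusted over the list alone, 4 after quantile normalization), with Lin28a (-1.42), the Nodal antagonist Lefty1 (-1.29; adjusted p = 0.0549 after quantile normalization), Nr0b1 (-1.26) and Sall4 (-1.05) lowered and Dppa5a (0.19) not passing. Their median was -0.36 (adjusted p = 2.48e-06; adjusted p = 0.0430 with an estimated correlation). Within run 3 the unadjusted medians were 0.61 and -0.26, and with the run as a block the adjusted p-values were 4.83e-13 and 2.23e-06. The feeder fibroblast list had 0.22 (adjusted p = 0.412) and 0.58 before subtraction within run 3.

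Immediate-early and dissociation genes had a median of 0.45 in KO at 24 h (8 raised, 11 raised and 1 lowered adjusted over the list alone, adjusted p = 0.000325; adjusted p = 0.359 with an estimated correlation), with Ccn1, Btg2, Jun (1.23) and Atf3 (1.16; adjusted p = 0.0763 after quantile normalization) raised and Ier2 (-0.39) and Jund (0.04) not passing. Integrated stress response genes had -0.33 (1 raised and 5 lowered, 1 and 6 adjusted over the list alone, adjusted p = 0.000455; adjusted p = 0.399 with an estimated correlation), with Slc7a5 (-1.24), Mthfd2 (-1.10) and Psat1 (-0.98) lowered and Hspa5 (0.07) and Asns (-0.23) not passing. Trophectoderm genes had 0.45 (16 genes, 3 raised, 4 adjusted over the list alone, adjusted p = 0.0204; adjusted p = 0.399 with an estimated correlation). They were the cadherin gene Cdh3 (0.92), Eomes (0.67) and Tfap2c (0.48), of which Eomes (adjusted p = 0.0519) and Tfap2c (0.0513) were not called after quantile normalization, while the keratins Krt18 (1.42) and Krt8 (1.05) varied between arrays and did not pass. With the run as a block the trophectoderm list was not called (adjusted p = 0.151). Primitive endoderm genes had 0.23 (2 raised, 3 adjusted over the list alone). The list's adjusted p was 0.0204, and 0.573 with an estimated correlation. Cited1 (1.22) and Lamb1 (0.77) were raised, while Sparc (0.39) and Lamc1 (-0.50) did not pass. Within run 3 the list's median was 0.36 before subtraction, while the feeder fibroblast list had 0.58 there.

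Hypoxia and glycolysis genes had 0.24 in KO (5 raised, 6 adjusted over the list alone, adjusted p = 0.0204; adjusted p = 0.620 with an estimated correlation), among them Slc2a1 (0.94), Hk1 (0.74) and Slc2a3 (0.59), while Ldha (-0.04) and Aldoa (0.08) did not pass. Epiblast and priming genes had -0.39 (1 raised and 2 lowered, 1 and 3 adjusted over the list alone, adjusted p = 0.0276; adjusted p = 0.359 with an estimated correlation), with Dnmt3b (-1.22) and Lef1 (-1.11) lowered, Nodal (0.41) raised and Dnmt3a (-0.69) not passing. Sterol synthesis genes had -0.32 (2 lowered, 1 raised and 2 lowered adjusted over the list alone, adjusted p = 0.0276; adjusted p = 0.547 with an estimated correlation), with Mvk (-1.19) and Fdps (-0.82) lowered and Hmgcs1 (0.05) and Fdft1 (-0.44) not passing. The sterol list was not called with the run as a block (adjusted p = 0.0854). Of all list calls in these comparisons, those of the p53 targets in WT and KO at 2 h and in KO at 24 h and of the pluripotency genes in KO at 24 h hold with an estimated correlation.

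At 24 h 1527 probe sets changed in WT, 952 up and 575 down (278 and 76 by at least 2-fold), and 1423 in KO, 888 up and 535 down. After quantile normalization the KO count was 1138, with 561 up and 577 down. The WT and KO sets, from different arrays, shared 493 raised and 274 lowered probe sets, and 0 went in opposite directions. For independent lists 47.7 and 17.3 would be expected, but these lists shared the estimate of the spread. Over all probe sets the 2 responses had r = 0.65. Without WT 24 h replicate 1 the WT count was 276, and without WT growing replicate 3 it was 972. The KO count was 225 without KO 24 h replicate 1, 587 without KO growing replicate 1 and 649 without KO growing replicate 3. Without the second day the counts were 646 and 431. The interaction at 24 h gave 0 probe sets in limma, with a smallest adjusted p of 0.204 and 851 at an unadjusted p under 0.05, and no list differed. The largest list difference in rank was that of the 2-cell-like genes (adjusted p = 0.0601).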

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

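Genes of the G2/M and mitosis list differed between the genotypes in their response to irradiation at 2 h (adjusted p = 0.01468 over 31 genes), but not with an estimated correlation (adjusted p = 0.750) or after quantile normalization (adjusted p = 0.527). The difference was small, with a median of -0.07 and no single gene passing. Over all probe sets the median of this interaction was 0.058 in the deposited scaling and -0.007 after quantile normalization. The list call thus depends on how the arrays are scaled, and the cause was not tested.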

How the results depend on the processing

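Of 43 list calls, 4 were kept with an estimated correlation, 15 with fry, 34 with the run as a block, 28 after quantile normalization, 26 with the filter at the 50th percentile and 33 without a filter, and 0 changed direction. No named gene that passed turned direction, and 198 of their calls were lost over the alternative settings and 259 over the arrays left out in turn. Some that did not pass changed sign. The cause was not tested for the values below.

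For KO against WT the number of probe sets in growing cells, at 2 h and at 24 h was 124, 198 and 35 with the replicate number as a fixed block, 69, 132 and 24 as a random block, and 144, 187 and 23 with the run as a block. Only in WT at 2 h against growing cells were the numbers taken to pair arrays; with them as a block 36 probe sets passed there (33 up and 3 down) and no list call was lost and no named gene changed its call. In the other comparisons the numbers were not taken as pairs, although some same-numbered arrays shared a run, and correlations were from -0.092 to 0.143 in growing cells, 0.097 to 0.174 at 2 h and 0.257 at 24 h for KO against WT. They were -0.061 to 0.276 for KO at 2 h, 0.098 to 0.117 for WT at 24 h and 0.024 to 0.027 for KO at 24 h. With array weights the 3 counts were 82, 229 and 7, without the second day 6, 4 and 5, and with only the groups compared 24 in growing cells and 3 at 24 h. In growing cells the count was 25 without a filter, and at 24 h it was 20 with the filter at the 50th percentile and 25 after quantile normalization. Without trend it was 24 in growing cells and 7 at 24 h, without the 2 arrays of high 18S signal 23 in growing cells and 41 at 2 h, and with a 2-fold minimum 19 and 30.

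For the responses to irradiation, using only the groups compared gave 17 in WT at 2 h and 583 in WT at 24 h. Leaving out the second day gave 15 in WT and 11 in KO at 2 h, and 646 in WT and 431 in KO at 24 h. A 2-fold minimum gave 354 in WT and 256 in KO at 24 h. Array weights gave 45 in KO at 2 h, and 1 for the interaction at 2 h, as did using only its groups.

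Leaving out 1 array at a time gave 6 to 58 for KO against WT in growing cells, 25 to 96 at 2 h and 8 to 22 at 24 h. It gave 17 to 39 for WT and 11 to 21 for KO at 2 h, 276 to 1732 for WT and 225 to 1525 for KO at 24 h. Each interaction had 0 to 1: 1 at 2 h without either KO 24 h array, and 1 at 24 h without WT growing replicate 2 or WT 24 h replicate 2.

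The primitive endoderm median for KO against WT was 0.31, 0.34 and 0.16 in growing cells, at 2 h and at 24 h. Adjusted p-values with fry, which tests for a shift of the list up or down and not against other genes, were 0.198, 0.130 and 0.246. With an estimated correlation they were 0.467, 0.471 and 0.388. With the run as a block the median at 24 h was 0.10 (adjusted p = 0.109). With 1 array left out the medians were 0.20 to 0.31, 0.055 to 0.45 and 0.005 to 0.46.

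The p53 target median in WT at 24 h was 0.53, with adjusted p = 0.0541 with an estimated correlation. That of pluripotency genes was -0.16, with adjusted p = 0.210. Leaving out 1 array gave p53 medians of 0.19 to 0.28 in WT and 0.31 to 0.38 in KO at 2 h. In WT at 24 h they were 0.44 to 0.76. In KO at 24 h they were 0.66 to 0.84 before subtraction of the median over all probe sets, against 0.775 with all arrays. Pluripotency medians were 0.03 to 0.16 for KO against WT in growing cells and -0.35 to -0.07 in WT at 24 h. In KO at 24 h they were -0.38 to -0.18 before subtraction, against -0.252 with all arrays.

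The G2/M and mitosis interaction at 2 h was -0.069, with adjusted p = 0.750 with an estimated correlation and 0.667 with fry. It was -0.028 after quantile normalization (adjusted p = 0.527) and -0.12 without the second day (adjusted p = 0.0809). Leaving out 1 array gave -0.14 to -0.017, with no call without WT growing replicate 3 (adjusted p = 0.0599), KO growing replicate 1 (0.0653) or WT 2 h replicate 1 (0.0692).

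The feeder fibroblast list turned direction for KO against WT in growing cells without WT growing replicate 3, an array of the second day, with a median of 0.29 (adjusted p = 0.0310) against -0.09 with all arrays. The range over the arrays left out was -0.36 to 0.29.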

Other observations

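A comparison of KO with WT pooled over the 3 states was chosen after the results of single states were seen, and its genes were chosen after their values. It took the 8 arrays of each genotype as independent, although same-numbered arrays of different states may share an experiment. If they do, its p-values are too small. It gave 733 probe sets, 357 higher and 376 lower in KO (216 and 238 genes), and the number was 243 without the second hybridisation day and 23 with a 2-fold minimum. Genes of the primitive endoderm were higher as a group (6 higher, 0 lower, 9 higher and 2 lower adjusted over the list alone, median 0.25, camera adjusted p = 0.000218; adjusted p = 0.227 with an estimated correlation). Besides Srgn (1.86) and Cubn (1.51) they included the endocytic adaptor Dab2, at 80.2 ± 35.2 in KO against 34.0 ± 8.29 in WT (0.91, adjusted p = 0.00125, n = 8 each), and the lineage regulators Gata6 (34.9 ± 10.7 against 17.8 ± 5.58, 0.59, adjusted p = 0.0178), Gata4 (0.53) and Sox7 (0.42). These last 4 did not pass in any single state.

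Epiblast and priming genes were higher too, with Dnmt3a (480 ± 149 against 234 ± 108, 1.15), Otx2 (0.83), Pou3f1 (0.49) and Foxd3 (0.46), a list median of 0.08 and adjusted p = 0.0202 (0.227 with an estimated correlation). FGF and ERK signalling genes had 3 higher and 1 lower (Etv4 1.14, Myc 0.47, Spred2 0.41 and Ier3 -0.36; list adjusted p = 0.0190, and 0.227 with an estimated correlation). Pluripotency genes were not shifted as a group (2 higher, 5 lower, adjusted p = 0.419), and the 5 lower were Nanog (544 ± 149 against 749 ± 157, -0.47, adjusted p = 0.0139), Dppa3 (-0.64), Klf2 (-0.48), Tcl1 (-0.69) and Lefty1 (-0.84). Gbx2 (0.61) and Jarid2 (0.40) were higher. Of the imprinted genes 4 were lower, among them Plagl1 (-1.14), without a call for the list (adjusted p = 0.150). With the run as a block this list was called (median -0.11, camera adjusted p = 0.0115). With an estimated correlation and no block its adjusted p was 0.331. Interferon response genes Ifitm1 (-0.97) and Ifi35 (-0.53) were lower as well (list adjusted p = 0.0372; 0.227 with an estimated correlation). Of the mitotic genes Mki67 (-0.41) and Ttk (-0.49) were lower and 1 was higher (list adjusted p = 0.232). Sterol synthesis genes had a median of -0.19 (adjusted p = 0.00275, and 0.227 with an estimated correlation). Visceral endoderm genes had 0.14 (2 higher, 0 lower, camera adjusted p = 0.0141, and 0.191 with an estimated correlation). Mesoderm and primitive streak genes had 0.15 and neuroectoderm genes -0.15 (camera adjusted p = 0.0219 each, and 0.227 with an estimated correlation). The parietal endoderm list was not called (-0.03, camera adjusted p = 0.932).

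All tests of this paragraph were chosen after the results were seen. The higher primitive endoderm genes could reflect fibroblasts left after the gelatin step, but over all states the feeder list differed by -0.002 (bootstrap interval -0.084 to 0.089). This came from opposite values in the runs: 0.14, 0.41 and 0.25 in runs 1, 2 and 3, and -0.39 and -0.52 in run 4. The intervals given here resample the genes of the list with the arrays held fixed. They do not measure the spread between samples. On the first day alone it was higher in KO by 0.138 (0.055 to 0.214), against 0.261 for primitive endoderm genes. No model with the feeder score was fitted within that day. Over all 16 arrays the primitive endoderm median was 0.254 with or without each array's feeder score in the model. There the feeder list hardly differed between the genotypes, so that model cannot decide whether fibroblasts contribute. Of 22 measured feeder genes, 0 of them in another list and 10 above the median of all genes in WT growing cells, the most abundant were Acta2, at 381 ± 36.5 in KO and 430 ± 203 in WT growing cells, and Tagln, at 253 ± 60.9 and 446 ± 293. With the hybridisation run as a block the primitive endoderm list kept a median of 0.206 (camera adjusted p = 0.001504). No test with this block used an estimated correlation, so the run is not excluded. With an estimated correlation and no block the adjusted p was 0.227. The primitive endoderm list was not above other genes in run 2 at 2 h (0.09 against 0.10) and was 0.01 in run 3 at 24 h. Exact permutation of genotype within states gave p = 0.001667 (2400 assignments, mean difference 0.33, n = 8 arrays per genotype). It exchanged arrays across runs and so says nothing about the run. It also took the 8 arrays of each genotype as independent, although same-numbered arrays may share an experiment. What remains open is a contribution of fibroblasts, an effect of the run, or a difference between the lines other than the inactivated allele. The labels do not say how many lines each genotype had.

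The tests of X-linked genes were also chosen after the results were seen. Of 315 X-linked genes 23 were lower in KO (7.30%) against 215 of 9920 autosomal genes (2.17%, Fisher's exact p = 1.122e-06), while 4 were higher (1.27% against 2.14%). One explanation might be fewer X chromosomes in KO cells, but all X-linked genes together differed from autosomal genes by -0.026. A halving of all their WT levels would give -0.72. The bootstrap interval, -0.048 to -0.003, resamples genes with the arrays held fixed and does not measure the spread between samples. A loss in a small share of cells stays open. Eif2s3y of the Y chromosome was present in both genotypes (99.3 ± 19.6 in KO and 88.9 ± 16.9 in WT, n = 8 arrays each), and Xist stood at 48.6 ± 9.39 and 44.7 ± 10.3. A regulatory effect of the knockout on these genes and a segment of X that differs between the lines both remain possible hypotheses.

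Neighbouring genes were grouped, and tests for them chosen, after the results were seen. Among genes called in the pooled comparison, 31 pairs were direct neighbours in the order of tested genes on GRCm38.p6, against a mean of 20 pairs in random placements (permutation p = 0.0099). Some pairs changed in the same direction and others in opposite directions. An example is chromosome 14, where Ccnb1ip1 (1.86) lies beside Ttc5 (0.40) and Supt16 (0.74) beside Rpgrip1 (-0.84). Strain differences in sequence under the probes are a candidate explanation that stays open: probe sets of 1 gene disagreed in 3 of 25 called genes beside another called gene (12%) against 2 of 177 others (1.13%, Fisher's exact p = 0.0143), but 2 of the 3 are Supt16 and Rpgrip1 of this example, and without its segment it was 1 of 23 (p = 0.308). Supt16 had 2.16 with 1 probe set and 0.74 with another (difference 1.42, adjusted p = 7.60e-05), and alternative transcripts remain open.

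The regrouping of arrays was likewise chosen after the counts were seen. For KO against WT in growing cells 1 of 10 splits of the arrays gave as many probe sets as the true one (44, highest other 0), and the same held at 2 h (70, highest other 0). For WT and KO at 2 h against growing cells it was 1 of 10 each (26, highest other 2, and 19, highest other 0). With 10 splits there are too few for a share under 0.05. For the pooled genotype comparison 1 of 100 splits reached 733, with 37 as the highest other. The interaction at 2 h had a count of 0, which all 100 of 100 splits must reach, so this decides nothing; the highest, 366, came from exchanging genotypes in growing cells only, which measures the genotype difference itself.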
